A study of Drosophila melanogaster with 4 samples.

How the data were processed

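Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to nuclei from the heads of Oregon-R flies, a wild-type laboratory strain of Drosophila melanogaster. The antibody was directed against H4K16ac, the acetylated form of a lysine in the tail of histone H4. The labels describe the flies as mixed adults and state no sex. The titles and the antibody name also carry a letter M that the labels do not explain, so it was not used. Per the labels' protocols, flies were grown in population cages, heads were collected by sieving, tissue was homogenised and fixed with formaldehyde, and chromatin was sheared by sonication before precipitation. The series holds 4 samples, namely 2 ChIP replicates and 2 input replicates of unprecipitated chromatin. Each input is labelled as the control of the ChIP with its number. Nothing in the labels says whether the replicates came from separate fly collections, so the spread between them may be technical.

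The processed data were 3 lists of regions made by the authors, 1 for each ChIP replicate and 1 combined list for the replicate set. No separate file of an input library was used here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers, and are 1-based. The region caller, its thresholds and the way in which the replicates were combined are not given in the sources used here. Each region carries a score set by the authors, which was above 0 for every region named as enriched and below 0 for every region named as depleted.

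The scale of the score was not stated and was inferred from the values: the deposited score was taken as a log2 value. Clusters often shared a score: 812 of 4051 did in replicate 1, 854 of 4431 in replicate 2 and 906 of 5728 in the combined list. Part of the scores differed by the logarithm of a ratio of whole numbers. With base 2 and 1 fixed offset per list, 13.7% of the scores of replicate 1, 11.2% of those of replicate 2 and 7.73% of those of the combined list equalled the logarithm of a ratio of whole numbers up to 60, within 1e-06. With natural or decimal logarithms at most 1.18% did in any list. Fewer scores matched with base 2 than were shared (555 against 812 in replicate 1), so not every shared score is such a ratio. In the combined list 442 of 5502 clusters under 10 kb matched with base 2, against 1 of 226 wider ones. For wide clusters the log2 scale is therefore carried over from the narrower ones. Whether the score is the mean or the peak of a region is not stated. The lists give no read numbers, so the sequencing depth of each library is unknown and no counting interval can be attached to a cluster. All scores and p-values of single clusters are therefore the authors' values. Tests used scores only within a list. Where scores of 1 region in several lists stand side by side, or are correlated between lists, they were not brought to a common scale, and their differences are not read as changes.

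Enriched regions (called clusters here) were kept as deposited and depleted regions were set aside. The last cluster on the X ran past the stated end of the sequence by at most 370 bp in each list and was trimmed there for covered lengths. The X was compared with the 4 large autosome arms 2L, 2R, 3L and 3R, whose lengths came from the file headers. Values were computed in each replicate list and are given as mean ± SD (n = 2). Overlap of the replicates was measured as the Jaccard index, the length covered in both lists divided by the length covered in either, and was tested by shifting replicate 2 around each arm 1000 times (circular-shift permutation test, one-sided). The ratio of covered shares was tested by shifting all clusters along the 5 large arms laid end to end 1000 times (two-sided). Medians of width and score were compared by permuting the X label over blocks of 100 kb, 10000 times (two-sided). These tests describe positions along the genome in these libraries and do not measure variation between flies. No test between groups of samples could be made, because only files of the ChIP group were used here. Overlap of 1 bp counted as shared unless stated otherwise.

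The procedures were tested on simulated cluster lists. Over 60 random placements of autosome-like clusters, the overlap test called 1, the ratio test 0 and the width test 5. The width test thus called 8.33% of them at a threshold of 0.05. These placements held no wide domains and no grouping of clusters along an arm, and used fewer shifts or permutations than the tests reported. They do not show how the tests behave on lists with wide X domains, and the score test was not simulated. The ratio test recovered 3.98 for a density on the X set to 4 times that of the autosomes, and the width test recovered 1.98 for widths set to 2 times. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

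The tests between the X and the autosomes and between the replicates, their alternatives and the rule for named regions were set before the data were examined. The width classes of 10 kb and 50 kb, the windows of 200 kb and 1 Mb, the unmarked stretches, the length outside wide clusters, the one-to-one matching of scores and the search for the scale of the score were chosen after. Named regions were the 10 clusters of highest score in the combined list that overlapped both replicates, and the 5 widest such clusters on the X and on the autosomes. Alternatives were leaving out a replicate, keeping the 50% of clusters with the highest score (ranked within a list), using the combined list, a stricter overlap, trimming 2 Mb at the centromere end of each arm, clusters per Mb, equal cluster numbers and merging clusters less than 500 bp apart. Comparisons at genes (marked gene ends and gene lists) had been planned and were not run. The gene table at hand is on release 6 of the genome, and coordinates were not moved between releases. Regions are therefore named by position, and the genes in them were not analysed here.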

Results

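H4K16ac was mapped in chromatin from adult fly heads with 2 ChIP replicates, each labelled with an input library as its control. The regions were called by the authors. In Drosophila this mark is placed by the acetyltransferase MOF. In males it is known to be laid down across the X by the MSL dosage compensation complex, and elsewhere it is found at active promoters. Replicate 1 held 4051 enriched clusters and replicate 2 held 4431 (mean 4241 ± 269, SD, n = 2). They covered 20.3 and 21.5 Mb, respectively. The median cluster was 2069 bp wide in replicate 1 and 2140 bp in replicate 2, and no replicate cluster was narrower than 1301 bp. The combined list held 5728 clusters over 26.3 Mb, with a narrowest cluster of 1001 bp. The lists carry no read numbers, so depth is unknown. The median score on the log2 scale was 0.64 in replicate 1, 0.65 in replicate 2 and 0.47 in the combined list.

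The main comparison the data allow is between the X and the autosomes. H4K16ac clusters covered 58.6% ± 0.222 of the 22.4 Mb of the X and 7.73% ± 0.869 of the 96.6 Mb of 2L, 2R, 3L and 3R (SD, n = 2). The X held 26.2% ± 0.413 of the clusters on these arms but 63.8% ± 2.69 of their covered length. The covered share of the X was 8.26 times that of the autosomes in replicate 1 and 7.01 times in replicate 2 (mean 7.63 ± 0.887, n = 2). In the circular-shift permutation test no shifted placement reached this ratio in either replicate (two-sided p = 0.001, the smallest that 1000 shifts can give). The combined list gave 69.8% for the X, 10.6% for the autosomes and a ratio of 6.61.

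**Figure D1:**
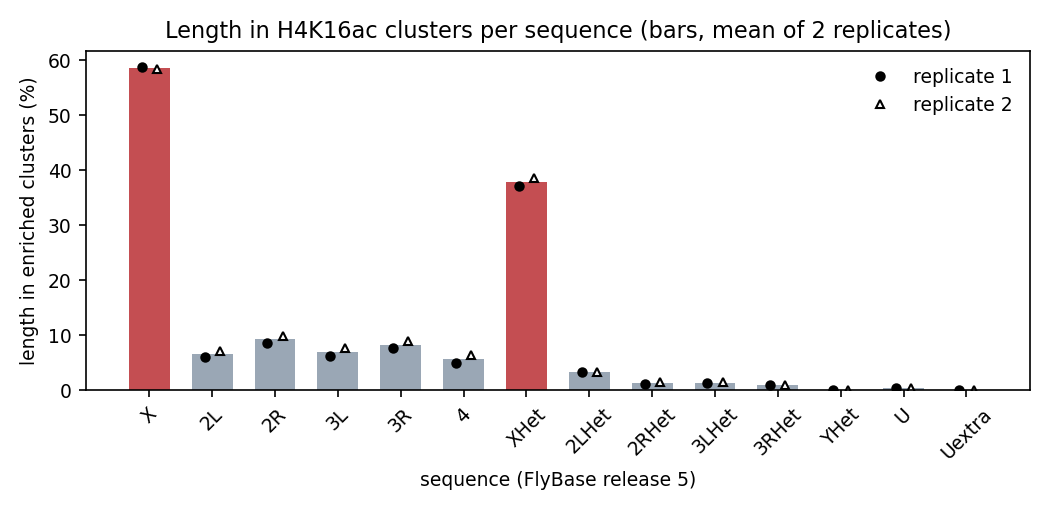
Length of each sequence of FlyBase release 5 that lies in enriched H4K16ac clusters, in percent; bars are means of both ChIP replicates, filled circles are replicate 1 and open triangles replicate 2, and red bars mark X sequences. The X arm stands at 58.6% and the X heterochromatin sequence at 37.9%, against 9.23% for the highest other arm, 2R.

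Among the autosome arms, 2R was covered most, at 9.23% ± 0.894, followed by 3R at 8.22% ± 0.853, 3L at 6.91% ± 0.944 and 2L at 6.61% ± 0.784 (SD, n = 2). This order held in each replicate, and the arms were not tested against each other. Chromosome 4, a small and largely heterochromatic chromosome, held 33 and 41 clusters in the replicates and was covered to 5.65% ± 1.04, below 2L in each replicate. In the combined list it was covered to 9.41%, above 2L at 9.09%, and in the 50% of clusters with the highest score to 1.66%. The median score on chromosome 4 was 0.44 in replicate 1 and 0.49 in replicate 2, against 0.55 and 0.57 on the 4 large autosome arms.

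Coverage of the X was high over most of its length. In windows of 200 kb the median covered share was 61.0% on the X (112 windows) and 6.64% on the autosomes (481 windows), as means of both replicates. The window from 15600001 to 15800000 on the X lay wholly in clusters. The most covered autosome window, from 19800001 to 20000000 on 2R, reached 33.1%. No autosome window reached the lower quartile of the X windows, 38.0%. The X was not covered evenly: 23 of its 112 windows were at or below the most covered autosome window, and 6 were at or below the autosome median. The longest stretches of the X without a cluster in either replicate ran from 21511324 to 21844253 (333 kb) and from 7243479 to 7550282 (307 kb), the latter with 2 combined clusters inside it. In bins of 1 Mb the X ranged from 34.6% (21 to 22 Mb) to 82.5% (11 to 12 Mb), while the highest such autosome bin, on 2R between 19 and 20 Mb, reached 17.3%.

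**Figure D2:**
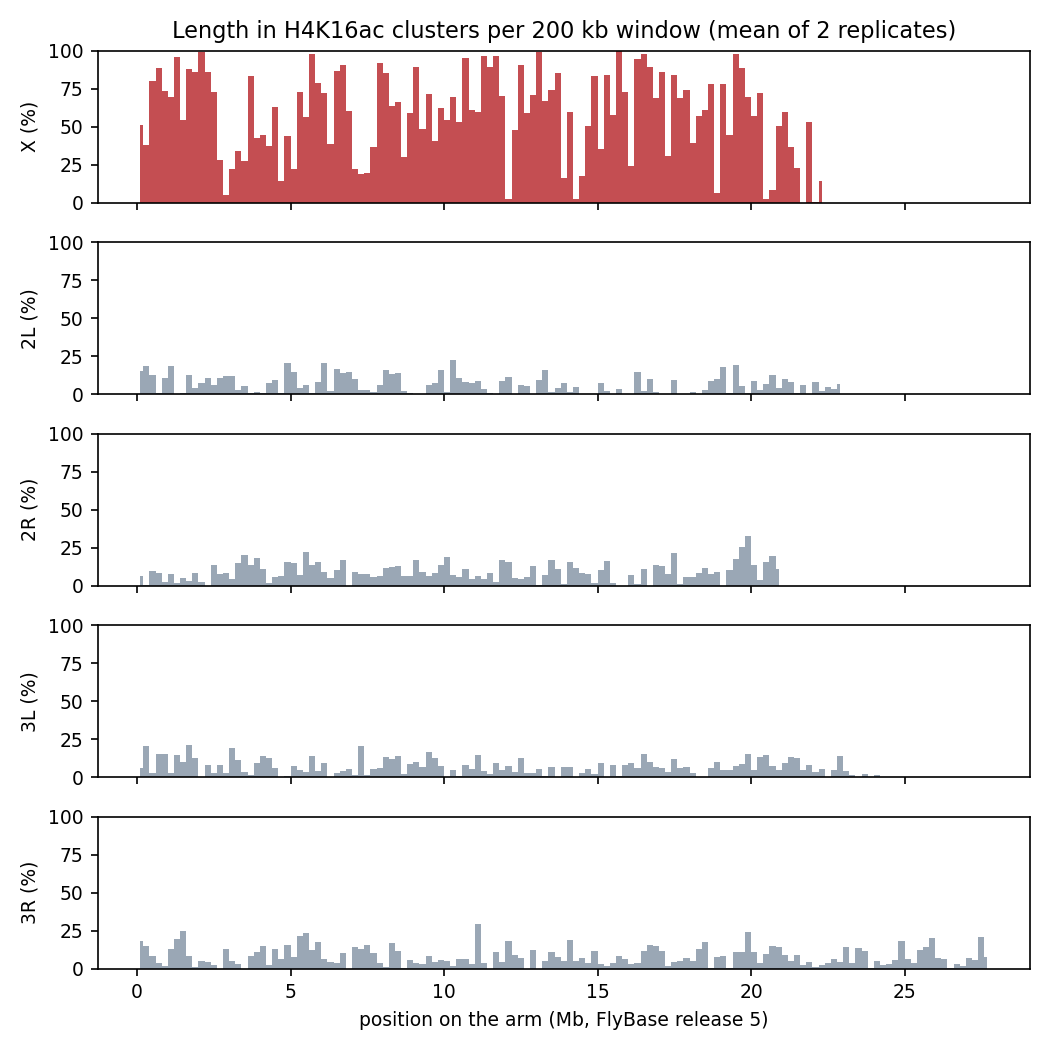
Percent of each 200 kb window that lies in H4K16ac clusters (y axis, 0 to 100, mean of both replicates) along the X and the 4 large autosome arms (x axis, Mb on FlyBase release 5). X windows have a median of 61.0% with local drops to 0, and autosome windows stay at or below 33.1%.

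The width of the clusters separated the X from the autosomes through a subset of very wide domains. Clusters of 10 kb or wider numbered 204 and 220 on the X in replicates 1 and 2, against 3 on the autosomes in each. They held 81.9% ± 0.535 of the covered length of the X and 0.478% ± 0.0254 of that of the autosomes (SD, n = 2). Clusters of 50 kb or wider numbered 72 and 76 on the X and 0 on the autosomes, and held 55.8% ± 2.08 of the covered length of the X. The mean cluster width was 12157 ± 618 bp on the X and 2442 ± 108 bp on the autosomes. The median cluster differed far less, at 2369 and 2413 bp on the X against 2036 and 2118 bp on the autosomes. The ratio of medians was 1.15 ± 0.017 (block permutation test, two-sided p = 0.0001 in each replicate, the smallest that 10000 permutations can give). The direction of this ratio was not stable: the combined list gave 0.949 (block permutation test, two-sided p = 0.0073).

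Narrow clusters covered more of the X in the length left to them, but this length is set by the mark itself. Taking out wide clusters shortens the X and hardly the autosomes, so the ratio had to come out higher than over the whole arms. Some narrow X clusters may be pieces of wide domains, which was not tested. Outside clusters of 10 kb or wider, 11.7 ± 0.111 Mb of the X and 96.6 Mb of the autosomes remained. Narrower clusters covered 20.4% ± 0.331 of this part of the X and 7.69% ± 0.867 of that of the autosomes. The ratio was 2.66 ± 0.257 (n = 2; circular-shift permutation test, larger two-sided p of both replicates 0.013), in an alternative chosen after seeing the data. Set against the whole arm length, which includes the length taken by wide clusters, the ratio was 1.39 ± 0.121 (larger permutation p of both replicates 0.0779). Counted per Mb of arm, the X held 48.3 ± 2.27 clusters and the autosomes 31.6 ± 2.16, a ratio of 1.53 ± 0.033 (larger permutation p of both replicates 0.022).

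**Figure D3:**
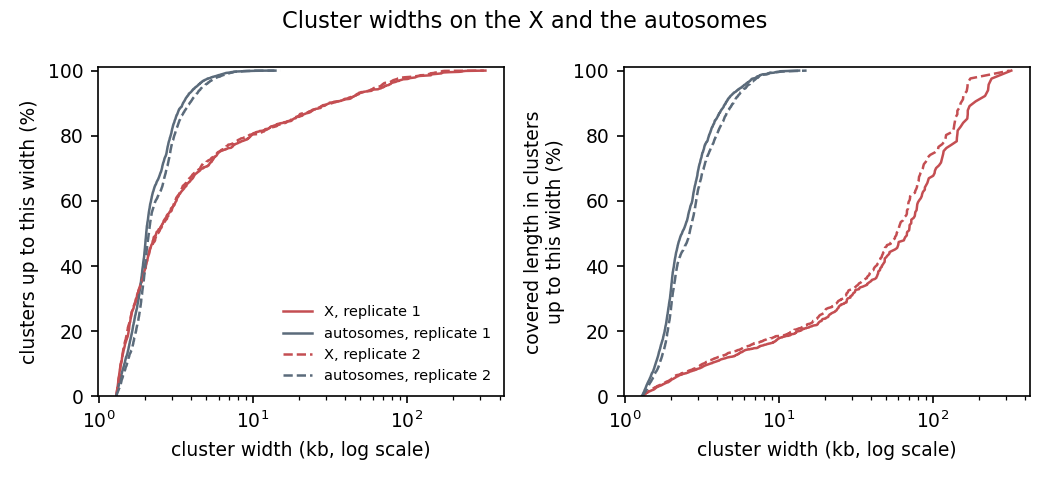
Cumulative percent of clusters (left) and of covered length (right) against cluster width in kb on a log axis, for the X (red) and the autosomes (grey) in replicate 1 (solid) and replicate 2 (dashed). Clusters of 10 kb or wider hold 81.9% of the covered length of the X and 0.478% of that of the autosomes.

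The widest clusters found in both replicates lay on the X and spanned 241 to 331 kb in the combined list. The widest ran from 15573663 to 15904202, with a score of 2.73. Its longest single cluster measured 323854 bp in replicate 1 and 316541 bp in replicate 2. The next 3 ran from 11643913 to 11937175 (score 2.51), from 12926216 to 13213083 (score 2.18) and from 6522255 to 6787167 (score 2.68). The fifth, from 13499383 to 13740444 (score 2.49), was 1 unbroken cluster in replicate 1 and 2 clusters in replicate 2. The region from 12926216 was split most, into 8 clusters in replicate 1 and 12 in replicate 2, which still covered at least 98.1% of it. The 5 widest autosome clusters were 10.4 to 17.9 kb. They lay on 2R from 5428958 to 5446870 (score 0.93) and from 19941917 to 19952658 (score 0.64), on 3R from 12072175 to 12084139 (score 0.71) and from 5902097 to 5912471 (score 1.01), and on 2L from 6958978 to 6969429 (score 0.80).

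Scores were also higher on the X, and so was the lowest score called. This was 0.34 and 0.36 on the X in replicates 1 and 2, against 0.089 and 0.014 on the autosomes. The calling thresholds are not given, so how far a higher floor on the X raises its median cannot be told. The median score was 0.88 and 0.79 on the X in replicates 1 and 2, and 0.55 and 0.57 on the autosomes, a difference of 0.28 ± 0.077 on the log2 scale (n = 2; block permutation test, two-sided p = 0.0001 in each replicate, the smallest possible). The combined list gave a smaller difference of 0.15. X clusters of 10 kb or wider had a median score of 2.29 ± 0.15 and narrower X clusters one of 0.79 ± 0.060. Autosome clusters under 10 kb had a median score of 0.56 ± 0.014. With clusters under 10 kb only, an alternative chosen after seeing the data, the difference was 0.23 ± 0.074 (block permutation p = 0.0001). In the 50% of clusters with the highest score it was 0.047 ± 0.069 and was not past the threshold (larger permutation p of both replicates 0.934), a selection on the score itself.

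Of the 10 clusters of highest score found in both replicates, 9 lay on the X. The highest, a 2.5 kb cluster on the X from 14176013 to 14178496, had a score of 4.25 in the combined list, 3.83 in replicate 1 and 4.02 in replicate 2. Its combined score equals the log2 of 20 to 1 at the scale fitted to that list. The fit leaves the scale open to whole-number factors, so the ratio itself is not determined. Such whole-number ratios were seen in 442 of the 5502 combined clusters under 10 kb and 1 of the 226 wider ones. The second was a 2.4 kb cluster from 5425376 to 5427781 on U, the collection of unplaced sequence. Its score was 2.87 in the list of replicate 1 and 4.52 in that of replicate 2. The remaining 8 were X clusters of 11.6 to 220 kb with combined scores of 2.87 to 3.12, among them the regions from 710957 to 722592 (score 3.12), from 21468913 to 21503070 (3.03), from 10996218 to 11079110 (2.94) and from 19445590 to 19665585 (2.94).

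The replicates placed their clusters largely in the same positions. The Jaccard index over the 5 large arms was 0.822, against a mean of 0.251 and a highest value of 0.368 over shifted placements (circular-shift permutation test, one-sided p = 0.001, the smallest that 1000 shifts can give). It was 0.875 on the X (highest shifted value 0.666) and 0.736 on the autosomes (highest shifted value 0.0649). On these arms, 88.9% of the clusters of replicate 1 overlapped replicate 2 and 81.3% of those of replicate 2 overlapped replicate 1. With a reciprocal overlap of 50% these shares were 78.2% and 71.6%. Replicate 2 held 3199 autosome clusters against 2904 in replicate 1, and 558 of its autosome clusters were its own against 195 in replicate 1. On the X, 244 clusters of replicate 1 and 249 of replicate 2 were found in that replicate only. By number, 76.7% and 77.7% of the X clusters and 93.3% and 82.6% of the autosome clusters were shared. By length the order was the other way, with 93.1% and 93.6% shared on the X and 92.1% and 78.6% on the autosomes, and neither difference was tested. The covered share of the X was nearly equal, at 58.7% in replicate 1 and 58.4% in replicate 2. Clusters present in 1 replicate only were narrower, with a median of 1549 bp in replicate 1 and 1621 bp in replicate 2, against 2145 and 2407 bp for shared clusters.

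Scores of clusters that matched one to one were correlated between the lists. Across 2460 such autosome clusters Pearson's r was 0.857 and Spearman's rho 0.823, and across 406 X clusters they were 0.978 and 0.760. These correlations are across clusters, which are not independent replicates.

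The combined list contained nearly all replicate clusters and added others. Of the replicate clusters, 99.7% in replicate 1 and 99.6% in replicate 2 overlapped a combined cluster. Of the 5728 combined clusters, 3163 (55.2%) overlapped both replicates, 1083 (18.9%) overlapped 1 and 1482 (25.9%) overlapped neither. The clusters found in both held 83.8% of the covered length and had a median width of 2904 bp, against 1282 bp for those found in neither. Clusters found in neither made up 42.1% of the combined X clusters (628 of 1490) and 19.6% of the autosome clusters (796 of 4063). By length the order was the other way, since they held 5.93% of the combined covered length on the X and 10.5% on the autosomes. Their median score was 0.41, against 0.57 for clusters found in both.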

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

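The tests in this part were chosen after the sequences had been seen to carry clusters. Sequences outside the comparison of the X with the autosomes also held clusters in both replicates. Those named here held more than 3 clusters in each, a limit for a count of 0 that says nothing of their background. The mean of both replicates was 13.5 clusters on the X heterochromatin sequence XHet, 15.5 on 2RHet, 15 on 3LHet, 7.5 on 3RHet and 16 on the unplaced sequence U. On 2LHet, 3 clusters in each replicate covered 3.30%, more than the share covered of 2RHet, 3LHet, 3RHet or U. YHet and Uextra held 0 clusters in every list.

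XHet stood apart from the other heterochromatin. Clusters covered 37.1% of its 204112 bp in replicate 1 and 38.6% in replicate 2, against at most 3.36% of any other heterochromatin or unplaced sequence. A single wide cluster is argued against as the whole cause: the longest cluster carried 59.4% and 58.0% of the covered length, and without it XHet was still covered to 15.1% in the replicate with the lower value. Chance of position stays open: 0 of 233 windows of its length on those sequences reached its share, but none of them holds as much covered length in all, so no window could have. Its share lay at a mean percentile of 21.6 among 109 windows of its length on the X arm. The 5th and 95th percentiles of those windows were 11.2 and 97.8% in replicate 1 and 11.7 and 96.8% in replicate 2. Any share in this wide range would have passed, so the check is weak. That this sequence carries the mark to the extent that stretches of the X arm do is a candidate explanation only. Unique placement of reads on heterochromatin and wrongly placed reads from the X arm remain open, and no biological explanation was tested, since the labels give no groups to test it with.

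The combined list also named 10 depleted regions of 1449 to 1794 bp. Of these, 8 lay on the large autosome arms, 2 on chromosome 4 and 0 on the X, with scores from -0.11 to -0.0036. Replicate 1 held 1 depleted region and replicate 2 held 0.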

How the results depend on the processing

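The covered share of the X stayed above that of the autosomes under every alternative run, past the threshold in each but 1 of them. The ratio, 7.63, became 16.1 in the 50% of clusters with the highest score, a selection that favours the X because scores are higher there. For clusters per Mb the ratio was 1.53. It fell to 1.39, short of the threshold, for clusters under 10 kb over the whole arm length, of which wide clusters leave 11.7 Mb on the X. Over the length outside wide clusters, which the mark itself sets, it was 2.66 and past the threshold. The ratio of median widths, 1.15, reversed to 0.949 in the combined list. In the 50% with the highest score it was 0.985 ± 0.065 (SD, n = 2), short of the threshold. That spread is wider than its distance from equal medians, so no direction can be given. With clusters less than 500 bp apart merged the ratio of medians was 1.32. It was 25.6 when N50, the width above which clusters hold 50% of the covered length, replaced the median. Among combined clusters found in both replicates it was 2.94. Clusters found in neither replicate, with median widths of 1312 bp on the X and 1270 bp on the autosomes, made up 42.1% of the combined X clusters. On the autosomes they made up 19.6%. The reversal in the combined list thus goes with its larger share of added narrow clusters on the X. Why these were called, and why the ratio was lower in the 50% with the highest score, were not tested. The difference in median score, 0.28, was 0.047 and short of the threshold in the 50% with the highest score. In the combined list it was 0.15. The selection of 50% leaves a mean of 2121 clusters per list by construction. The share of clusters overlapping the other replicate fell from 85.1% to 74.9% with a reciprocal overlap of 50%. The share of combined clusters found in both replicates, 55.2%, was 72.4% in the 50% with the highest score and 51.5% when 50% of the combined cluster had to overlap. Leaving out a replicate left 61.6% to 67.8% overlapping the remaining one, which asks for 1 list in place of both, and changed no call on the X. All 12 covered shares per sequence moved by more than the SD between replicates, 6 up in the combined list and 6 down in the 50% with the highest score. The downward direction was fixed in advance, since dropping clusters can only lower a covered share. Leaving out 1 of 2 replicates cannot move a mean by more than the SD and tests nothing here. Of 40 scores of named regions taken from a single replicate, 18 differed by as much from the combined score, 16 of them upward, on lists not brought to a common scale. Replicate overlap has no value from 1 list. N50, both settings with clusters under 10 kb, clusters found in both replicates and clusters on the large arms were chosen after seeing the data. The planned comparisons at gene ends and gene lists were not run for want of an annotation on release 5. No paired analysis was possible because only files of the ChIP group were used here, so no 2 groups could be compared. Depth is unknown: at the low end, cluster calls and scores depend on read numbers that the lists do not hold.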

Other observations

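Of the tests in this part, the pooled comparison of scores from 1301 to 2000 bp was fixed before its result was seen, and the others were chosen after. The longest stretch without a replicate cluster was longer on each large autosome arm than on the X. No replicate cluster lay in 563 kb of 2R (15559414 to 16122865), 521 kb of 2L (16888549 to 17409702), 510 kb of 3L (18104144 to 18614047) or 405 kb of 3R (2486713 to 2891684). The combined list had 3 clusters inside the stretch of 2R, 3 inside that of 2L and 0 inside those of 3L and 3R, and the genes in these stretches were not analysed here.

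The combined list goes down to 1001 bp and the replicate lists to 1301 bp, and 52.8% of the 1482 combined clusters that overlap neither replicate list are narrower than that limit (Wilson 95% interval 50.2 to 55.3%), so the lower width minimum may account for those and not for the other 700. Weakness was judged here by the score alone, a ratio that does not show how many reads lie behind a cluster. Support by few reads therefore stays open at every width. From 1301 to 2000 bp, with widths matched only to this range, a lower score is argued against on the autosomes. The median score of 329 such clusters there was 0.026 above that of 446 found in both replicates (95% bootstrap interval 0.0085 to 0.039). On the X a lower score stays open, with 256 against 11 clusters and a difference of 0.0065 (-0.040 to 0.074). The pooled difference of 0.097 decides nothing, since X clusters score higher and make up 256 of 605 on one side and 11 of 465 on the other. The 95 wider ones had a median score lower than that of clusters found in both, with a difference of -0.14 (-0.17 to -0.11). Widths were not matched there, and the X and the autosomes were pooled although X clusters score higher. This comparison cannot separate weakness from width and chromosome, so weakness stays open for them. For the narrower ones (difference -0.058) it stays open, since only 1 cluster of that width was found in both, and no biological explanation was tested.

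The second pattern is a set of 10 combined clusters with a score of at least 2 that overlap neither replicate, 1 of them on the X. They are 1001 to 1062 bp wide, and 4 share the score 2.92, at the fixed scale of the list. At that scale all 10 scores (100%) are the log2 ratio of whole numbers up to 16, against 8 of the 231 other clusters of these widths found in neither replicate (3.46%). The scale was fitted to this same list and is open to whole-number factors, so the whole numbers themselves are not determined. A candidate explanation is that these 10 clusters rest on few reads, which the lists cannot show directly. No biological explanation was tested for them.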
